A study of Homo sapiens with 4 samples.

How the data were processed

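The series holds 4 two-colour arrays of A549 cells, 1 for each of 12, 24, 48 and 96 h after transfection with a miR-375 precursor or a negative-control precursor. Per the labels, the miR-375 RNA was labelled with Cy5 and the control RNA with Cy3 on every array, with no dye swap. Arrays were Agilent whole human genome arrays (44K), read with Agilent Feature Extraction 9.5.1.1, and probe positions are those of the build (hg18) named in the file headers. Per the file headers, the scanner files give spot signals and local backgrounds as intensity, Feature Extraction's own background-subtracted, detrended and dye-normalised signals as intensity, and their quotient as log10 of Cy5 over Cy3. Flags per spot, such as well above background, are of another kind (other), per the file headers. The deposited series matrix holds a linear ratio per probe. Its column medians were 0.994, 0.999, 0.997 and 0.995, and between 12247 and 13474 of its 41000 probes were null by a rule that is not stated. Each of its columns had a correlation of 0.941 to 0.984 over probes with its own array's processed ratio and of at most 0.512 with any other array's.

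Each array had 45015 spots, of which 43376 were not controls, and no saturated spots (0). Between 146 and 152 outlier spots per array were left out. Mean spot signals were corrected against the median local background with normexp (offset 50), log2 ratios were fitted with loess within each array with control spots at weight 0, and repeated spots of a probe were averaged. In Agilent's processed signals the 10 spike-in control sequences had log2 ratios from -2.51 to 3.39, each varying by 0.0896 to 0.214 over the arrays. All of them were lowest at 12 h. Whether such a shift between arrays enters the ratios of genes, and so the changes from 12 h, was not tested. Probes were named from their accession in the RefSeq gene table of the GRCh38.p14 assembly (23958 probes), from their symbol or a synonym (3782), or kept the array's own name (13260). A probe was tested when it was well above background in at least 1 channel on at least 2 arrays, which left 24751 probes, and the brightest tested probe on average stood for its gene. This gave 18074 genes or transcripts, 12454 of them with a gene name and 5620 with the array's own name, and 4996 had more than 1 tested probe. Work was done in R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8), and plots in Python 3.11.15 with matplotlib 3.10.9.

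The mean log2 ratio over the 4 times was tested against 0 in limma with an intercept and moderated variances, and the slope on log2(hours) in limma with 2 residual degrees of freedom. P-values were adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05. With 1 array per time, the spread in these tests is that between times and not between replicate cultures, and a probe's dye bias is part of the mean but cancels in the slope if it is the same on every array. Genes with at least 2-fold differences were counted per array without a test. A channel that was not well above background gives a bound only, computed against the lowest level called well above background on that array or the channel's own signal, whichever was higher. Where the channel's own signal was used, the bound equals the computed ratio. As that level is the lowest of any probe, these bounds are approximate and not strict limits.

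Before the data were examined, 21 gene lists were fixed, and the 20 with at least 5 tested members were tested with camera (correlation 0.01, two-sided, adjusted over lists), with camera at an estimated correlation, with fry, and against 10000 random lists of like brightness at each time. No call of camera held with an estimated correlation. For the slopes of neuroendocrine markers and the microRNA machinery that correlation was -0.075 and -0.016, below the preset one. A higher correlation is therefore not why those calls were lost. With an estimated correlation camera uses the residual degrees of freedom (2 in the slope). A lost call alone thus does not show that a list did not move. Of the lists called in the mean, only the ribosomal one passed in fry (adjusted p = 0.0293), and of those called in the slope only the neuroendocrine one (adjusted p = 0.028). Fry tests whether a list's genes move one way on balance and does not compare them with other genes. The rule for named genes, fixed at the same time, took YAP1, the 12 largest falls and 12 largest rises in the mean among called genes with 1 sign on all 4 arrays, up to 4 members of each list with the largest means, the 5 steepest slopes each way, and the 3 largest differences each way on each array. Some genes that this rule took are left out of the text. The other genes named in the text are list members or genes at least 2-fold different on an array, and they were chosen after their values were seen. The number of bins for matching on brightness was raised from 20 to 200 after the percentiles had been seen.

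The tests were tested on simulated data made from the 18074 genes. A mean change of 0.3 was recovered for 62.7% of the changed genes, one of 0.5 for 83.6% and one of 1 for 100%, with 4.09% false calls. Slopes of 0.2, 0.4 and 0.7 were recovered for 32.8%, 71.6% and 92.4%, with 2.96% false calls. Of 20 simulated lists shifted by 0.15, all were recovered. Each gene was simulated independently of the others and without dye bias. These rates therefore do not cover correlated genes or dye bias. In the measured data the estimated correlation in the mean ran from -0.064 for alveolar and airway markers to 0.64 for G2/M genes. For reported targets it was 0.24. Alternatives changed the normalization, offset, filter, probe rule, moderation, fold threshold, time scale and list correlation, or left out each time point. The planned comparison of genes with and without a miR-375 seed match was not run, because no transcript sequences were provided.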

Results

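A549 cells, an established line from a human lung adenocarcinoma, were transfected with a precursor of the microRNA miR-375 or with a negative-control precursor, and RNA was collected 12, 24, 48 and 96 h later. MicroRNAs bind messenger RNAs by short complementary sites and lower the level or the translation of those they bind, and the stated purpose of the series was to look for candidate targets of miR-375. At each time, RNA of the miR-375 cells was labelled with Cy5 and RNA of the control cells with Cy3, and both were hybridised to 1 two-colour whole-genome array. The series holds 4 arrays, 1 per time point, all with the same dye orientation, so no time point has a replicate and a probe's own dye bias remains in every ratio. Each value below is a log2 ratio of miR-375 cells over control cells, and an SD is the spread over the 4 times (n = 4). Between 57.9% and 61.4% of non-control spots were well above background in the Cy5 channel and between 57.7% and 60.3% in the Cy3 channel, and 18074 genes or transcripts were tested. Repeated spots of a probe had a median SD of 0.0341 to 0.0373 (log2) on the 4 arrays, while the SD over genes ran from 0.131 at 12 h to 0.187 at 48 h. The number of arrays limits the precision of what follows.

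The first question was whether transcripts already reported as miR-375 targets were lower in the transfected cells. Of 30 such genes measured, 14 were lower in the mean over the 4 times, 1 (PDPK1, a kinase of insulin signalling) was higher and 15 did not pass the test. SEC23A, a coat protein of vesicles leaving the endoplasmic reticulum, was lowest, at -0.24, -0.54, -0.66 and -0.34 at 12, 24, 48 and 96 h (mean -0.44 ± 0.19 SD, n = 4, limma adjusted p = 0.00593). ERBB2, a receptor tyrosine kinase, had a mean of -0.40 ± 0.09 (SD), although only 1 of its 2 tested probes was lower. CAV1, the main protein of caveolae, had a mean of -0.36 ± 0.09 (SD) and MTDH, an oncoprotein of several carcinomas, of -0.32 ± 0.20 (SD). The list's median was -0.02 at 12 h, -0.24 at 24 h, -0.24 at 48 h and -0.14 at 96 h. At 12 h it lay at percentile 21.1 of 10000 random lists of like brightness, and at the other 3 times it lay below all of them. The list fell in the camera test of the mean (adjusted p = 1.77e-05, 20 lists). The call was lost with an estimated correlation (adjusted p = 0.925 with an estimated correlation) and without loess (adjusted p = 0.128). Its slope with time was not called (adjusted p = 0.0671), but was called with 12 h set against the later times (5.79e-05) and without the 24 h (0.00777) or 96 h array (5.62e-05). Adjusted over the list alone, 17 members were lower and 1 was higher. The list was drawn from the literature, and YAP1 may have been chosen by the study from these same arrays, so YAP1 is not independent evidence of the direction.

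YAP1, the transcriptional coactivator held in check by the Hippo pathway, was lower on all 4 arrays, at -0.28, -0.36, -0.34 and -0.23 (mean -0.30 ± 0.06 SD, n = 4, 0.812-fold, limma adjusted p = 0.00442). Both of its probes were lower. Its slope with time was not called (0.02 per doubling of the hours, limma adjusted p = 0.85). A dye bias that is the same on all arrays therefore cannot be told apart from an effect of miR-375 on YAP1. The probe that stands for the gene lies on chromosome 11 at 101605794 to 101605853 (hg18). The call ended when limma tested against a 1.2-fold change, and without loess, where the mean was -0.06. That setting moved the median of all genes to 0.22, and YAP1 minus that median was -0.28, against -0.31 with loess. Among 22 measured components of the Hippo pathway, 5 were lower, 2 were higher and 15 did not pass. The lower ones included VGLL4, a competitor of YAP1 for TEAD factors (-0.28 ± 0.10 SD), TAOK3, a kinase upstream of the pathway (-0.23 ± 0.14 SD), and WWTR1, the YAP1 paralogue TAZ (-0.15 ± 0.10 SD). The higher ones were TAOK2 (0.16 ± 0.04 SD) and FAT4 (0.12 ± 0.04 SD), the latter well above background on only 2 of the 4 arrays in the Cy5 channel and on 1 in the Cy3 channel. As a list these components were not called (camera adjusted p = 0.194). The 20 measured genes that respond to YAP and TEAD factors went both ways, with 3 lower, 6 higher and 11 not passing (camera adjusted p = 0.867). CCN2, a growth factor-like matrix protein and standard YAP readout, was higher (0.20 ± 0.09 SD), as were IGFBP3 (0.30 ± 0.09 SD), CCDC80 (0.28 ± 0.13 SD) and DOCK5, for which 1 of 2 probes was higher (0.30 ± 0.16 SD). NUAK2 (-0.26 ± 0.14 SD), CRIM1 (-0.24 ± 0.15 SD) and NT5E (-0.13 ± 0.03 SD) were lower. CCN1 was at -0.03 ± 0.03 (SD) and did not pass.

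At the main settings, the differences that reached 2-fold on an array were mostly late and in the direction of higher levels in miR-375 cells. The late timing did not hold with every processing. Computed log2 ratios reached 1 for 4 genes or transcripts at 12 h, 3 at 24 h, 7 at 48 h and 12 at 96 h, and -1 for 1 at 48 h, with no test because each time has 1 array. With ratios over a dim channel held at their bound, 2, 2, 6 and 11 were at least 2-fold higher and 1 was lower. Those at 12 h were MED18 and THC2667890 (at least 2.18-fold), those at 24 h MED18 and ZDHHC15 (at least 2.57-fold), and the lower one at 48 h was the transcript THC2578705, at least 5.12-fold lower with a dim Cy5 channel. CHGB (chromogranin B, a cargo protein of secretory granules) went from 0.14 at 12 h to 0.51, 1.76 and 2.16 at 24, 48 and 96 h, a 4.47-fold difference at 96 h. STMN3, a tubulin-binding protein of neurons, was at 0.00, 0.71, 1.72 and 1.77. DISP2 reached 1.39 at 48 h, and NKAIN1 and CLRN3 were over 2-fold higher at 48 and 96 h. At 96 h ACOX2, a bile acid oxidase of peroxisomes, was 2.18-fold higher, PRG4 (lubricin) 2.16-fold and AHSG (fetuin A, a liver plasma protein) 2.16-fold. SERPINA10 was 2.21-fold higher at 48 h. SCG3 (secretogranin III) was not well above background in the control channel and was at least 2.52-fold higher at 96 h. For AP3B2, a neuronal adaptor subunit with a dim control channel too, the bound at 96 h was only its computed ratio, 2.27-fold. MED18, a subunit of the Mediator complex, ran the other way in time, at 1.23 and 1.07 at 12 and 24 h and 0.19 and 0.18 later. With Agilent's own processed signals, the counts of computed ratios either way were 49, 61, 81 and 44. They were 20, 34, 39 and 21 with offset 0 and 39, 49, 73 and 39 with the series matrix. In these settings the counts were highest at 48 h and not at 96 h. At 1.5-fold, with the main processing, they were 21, 55, 140 and 133. Of these 20, 42, 79 and 121 were higher and 1, 13, 61 and 12 lower.

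**Figure D1:**
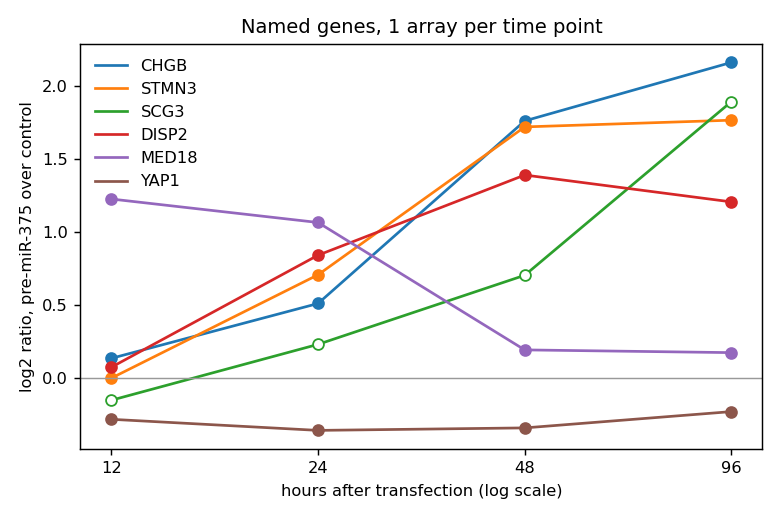
Log2 ratio of miR-375 over control cells (vertical axis) against hours after transfection on a log scale (horizontal axis) for 6 genes, with 1 array per point and no error bars because no time has a replicate. Open circles mark points where at least 1 channel was not well above background. CHGB reached 2.16 at 96 h, MED18 started at 1.23 and YAP1 stayed between -0.36 and -0.23.

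As a list, neuroendocrine markers had log2 ratios that rose with time, but not in every member. Only 12 of the 24 listed markers were tested, so the list speaks for these alone. Of these 12 measured markers, 8 had a positive slope and 4 a negative one, and the list's median went from -0.08 at 12 h to 0.13, 0.17 and 0.37. Apart from CHGB and SCG3, the list holds CPE, a prohormone-processing carboxypeptidase (-0.08, 0.13, 0.34 and 0.55). It also holds DDC, the decarboxylase that makes dopamine and serotonin (-0.10, -0.14, 0.13 and 0.56), and SYT1, a synaptic vesicle calcium sensor. SYT1 was 1.56-fold higher at 48 h by its computed ratio, over a dim control channel. CHGA, chromogranin A, was at 0.48 at 96 h. The negative slopes were those of ENO2, SNAP25, UCHL1 and PCSK1. The list rose with time in camera on the slope per doubling of the hours (median slope 0.15, adjusted p = 8.81e-04), a call lost with an estimated correlation (adjusted p = 0.711 with an estimated correlation) and without a filter on dim probes (adjusted p = 0.106). Of the 9 members well above background in both channels on all 4 arrays, 5 rose with time and 1 fell, adjusted over the list alone, and their medians were -0.07, 0.11, 0.13 and 0.31. In the mean over the 4 times, 2 members were higher and 10 did not pass, and the list was not called (adjusted p = 0.0854), but it was called without the 12 h array (adjusted p = 0.0169).

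Genes of G2/M and mitosis fell with time as a list after miR-375 transfection relative to control. Of 30 measured genes of G2/M and mitosis, 27 had a negative slope, and the list's median went from 0.02 at 12 h to -0.04, -0.23 and -0.20. Examples, chosen after their values were seen, are ASPM, a spindle pole protein (0.35, 0.14, -0.11 and -0.25), MKI67, the source of the Ki-67 proliferation antigen (0.26, -0.02, -0.03 and -0.28), and CENPF, a kinetochore protein (0.32, -0.22, -0.31 and -0.36). The list's slope fell in camera (median slope -0.08, adjusted p = 1.37e-09; adjusted p = 0.919 with an estimated correlation), and 11 members fell adjusted over the list alone. In the mean, 7 members were lower and 23 did not pass, and the list was called lower (adjusted p = 9.18e-05; 0.925 with an estimated correlation), a direction that turned without loess (adjusted p = 0.426). BIRC5 (survivin) had a mean of -0.26 ± 0.11 (SD), CDK1 of -0.23 ± 0.06 (SD), UBE2C of -0.23 ± 0.08 (SD) and KIF23 of -0.23 ± 0.19 (SD). Of 30 genes of DNA replication and S phase, 9 were lower, 1 was higher and 20 did not pass, with medians of -0.05, -0.11, -0.17 and -0.01. CDT1, which licenses replication origins, had a mean of -0.39 ± 0.12 (SD), and the nucleotide synthesis enzymes TYMS and TK1 had means of -0.33 ± 0.19 (SD) and -0.29 ± 0.16 (SD). GINS3 had a mean of -0.27 ± 0.09 (SD). This list was called lower in the mean (adjusted p = 4.34e-04; 0.925 with an estimated correlation), turned direction without loess (adjusted p = 0.287) and was not called in the slope (adjusted p = 0.4). The slope fell past the threshold without the 96 h array (adjusted p = 2.1e-04), with 12 h set against the later times (0.0411) and without loess (0.00297).

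**Figure D2:**
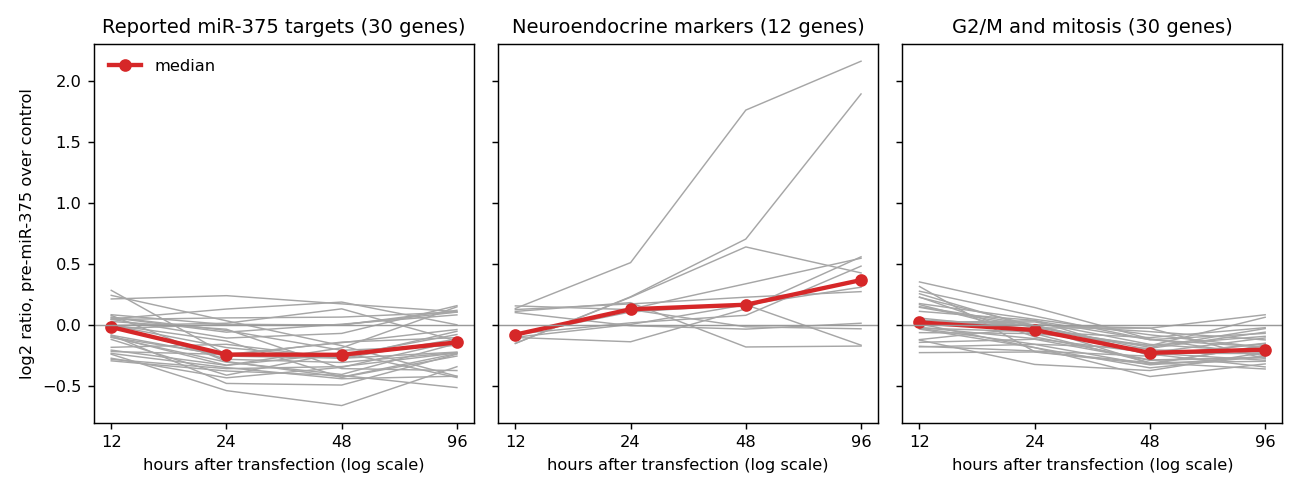
Log2 ratio of miR-375 over control cells (vertical axis) against hours after transfection on a log scale (horizontal axis) for the members of 3 gene lists, each grey line a gene and the red line the list's median over 1 array per time, after loess. The medians at 48 h were -0.24 for reported targets, 0.17 for neuroendocrine markers and -0.23 for G2/M genes, whose mean over the 4 times turned positive without loess.

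Across all genes, 1715 were lower and 2204 higher in the mean over the 4 times (limma adjusted p under 0.05 in 18074 genes), but most of these differences were small. Of the calls, 2854 (72.8%) had at least 1/2 of their mean at 12 h, with the same sign. A probe's dye bias that is the same on all arrays would be called in this test too. It was not separated from an effect of the transfection. Among genes well above background in both channels on all 4 arrays, a mean change of at least 1.2-fold was found for 332 lower and 555 higher genes, and of at least 1.5-fold for 3 (BC013025, FLJ38359 and MAT2B) and 10. The largest falls with a gene name were in MAT2B, a subunit of the enzyme that makes S-adenosylmethionine (-0.59 ± 0.14 SD, 0.666-fold), CCDC117 (-0.58 ± 0.03 SD, with 1 of its 2 probes lower), MISP, an actin-bundling protein of mitotic spindle positioning (-0.58 ± 0.08 SD), CXCL1, a neutrophil chemokine (-0.57 ± 0.19 SD), and PSIP1, a chromatin-binding protein (-0.53 ± 0.27 SD). EFTUD2, a GTPase of the spliceosome (-0.52 ± 0.15 SD), SPECC1 (-0.52 ± 0.21 SD) and ACSL3, a fatty acid-activating enzyme (-0.51 ± 0.15 SD), followed. The features BC013025, FLJ38359, THC2572820 and LOC649545, which keep the array's own names, had means between -0.65 and -0.52. Among the 12 largest rises, those well above background in both channels on all 4 arrays were CHGB (1.14 ± 0.97 SD), STMN3 (1.05 ± 0.85 SD) and DISP2 (0.88 ± 0.58 SD). The means of these 3 lost their calls without the 48 h array (0.94, 0.82 and 0.71) and without the 96 h array (0.80, 0.81 and 0.77), and that of STMN3 also without the 24 h array (1.16). The other 9 had a control channel not well above background on any array, except DMRTC1, whose control channel was above on 1 array. Their means are therefore ratios over a dim channel, and their sizes are not known. These 9 are ZDHHC15, at least 2.57-fold higher at 24 h, THC2667890, at least 2.18-fold higher at 12 h, and BC045677, THC2540497, THC2684446, AK127258, ARL11, DMRTC1 and C12orf42. Without loess 12095 genes were called higher and 7.86% of the calls were lower, against 43.8% here, while with Agilent's processed signals and the series matrix the lower genes were the majority (52.5% and 52.2%). In that setting 25 named genes turned from below 0 to above 0, among them CDT1, TYMS, BIRC5, HERPUD1 and CDH1, but 19 of the 25 stayed below its median of all genes, 0.22. Without the 24 h array 476 genes were lower and 680 higher, without the 48 h array 429 and 585, and without the 96 h array 964 and 1244, while limma against a 1.2-fold change called 1 and 6.

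The size of the slope with time was tested separately, because a dye bias that is the same on all arrays cancels in it. No single gene passed in limma over all genes (0 genes, lowest adjusted p = 0.162, 2 residual degrees of freedom). At an unadjusted p under 0.05 there were 2618 genes, where chance would give 904 on average. Genes measured on the same 4 arrays move together, so this count can lie far from 904 without any trend. The steepest positive slopes, which did not pass, belonged to CHGB (0.73 per doubling of the hours), STMN3 (0.63), ACOX2 (0.40), AHSG (0.40) and SCG3, which has only bounds at 48 and 96 h, and no usable ratio at 12 and 24 h, because its channels were not well above background. The steepest negative slopes belonged to MED18 (-0.40), CRYAB, a small heat-shock protein (-0.31), COL12A1, a fibril-associated collagen (-0.26), ANXA8 (-0.24) and PHLDB2 (-0.23), and none of them passed. Leaving out the 12, 24, 48 or 96 h array left 10, 7, 3 and 4 genes past the threshold, with hours in place of log2(hours) it was 2 and without loess 33.

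As a list, interferon-response genes were higher in the miR-375 cells, although most members did not pass alone. Of 21 measured, 6 were higher, 1 was lower (IFI35) and 14 did not pass, and the list's median was 0.03, 0.18, 0.14 and 0.19 at the 4 times. IFI6 had a mean of 0.41 ± 0.26 (SD), IRF9, the DNA-binding part of the interferon-stimulated transcription factor, of 0.35 ± 0.12 (SD) and OAS3, an antiviral synthetase, of 0.30 ± 0.15 (SD). IFIT1 went from -0.09 at 12 h to 0.57 at 96 h. The list rose in the mean (camera adjusted p = 0.0231; 0.925 with an estimated correlation) and in the slope (adjusted p = 0.0122; 0.919 with an estimated correlation). The call of the mean was lost without the 96 h array (adjusted p = 0.0989), without loess (0.558) and with all probes of a gene averaged (0.0517), and that of the slope without the 12 h array (0.367), with Agilent's processed signals (0.0868) and with the series matrix values (0.0821).

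Genes of hypoxia and glycolysis rose with time as a list (median slope 0.04, camera adjusted p = 0.00315; 0.919 with an estimated correlation), with 19 of 22 slopes positive, though the call was lost without the 96 h array (adjusted p = 0.164), with Agilent's processed signals (0.0572) and with 12 h set against the later times (0.167). In the mean 2 were higher, namely PFKFB4, a regulator of glycolytic flux (0.32 ± 0.20 SD), and ALDOC, an aldolase (0.18 ± 0.10 SD), and the list was not called (adjusted p = 0.411). Genes of the microRNA machinery fell with time as a list (median slope -0.04, adjusted p = 0.00599; 0.711 with an estimated correlation), a call lost without the 12 h array (adjusted p = 0.233). DICER1, the nuclease that cuts precursor microRNAs, was higher in the mean (0.36 ± 0.16 SD) with values of 0.47, 0.45, 0.40 and 0.12, and AGO4 was higher (0.23 ± 0.12 SD), while TNRC6B, for which 3 of 4 probes were lower (-0.21 ± 0.16 SD), DROSHA (-0.17 ± 0.06 SD) and AGO2 (-0.15 ± 0.07 SD) were lower. In the mean 2 of its 21 members were higher and 3 lower, and the list was not called (adjusted p = 0.867).

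Of 35 cytosolic ribosomal protein genes, 20 were higher, 1 was lower and 14 did not pass, with list medians of 0.18, 0.11, 0.12 and 0.18. RPS16 had a mean of 0.36 ± 0.03 (SD). RPS2 (0.44 ± 0.06 SD) and RPS14 (0.32 ± 0.05 SD) had higher values in 3 of 6 and 2 of 4 probes. The list rose in camera (adjusted p = 5.47e-06; 0.925 with an estimated correlation), but its direction turned with Agilent's processed signals (adjusted p = 0.887) and the call was lost with the series matrix values (0.814). These genes are among the brightest on the array, and against random lists of like brightness the list lay at percentiles 85.6, 25.3, 17 and 22.8 at the 4 times. That matching used 200 brightness bins, chosen after the percentiles with 20 bins had been seen (100, 99.8, 99.1 and 99.9).

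The remaining lists were called neither in the mean nor in the slope, but without the 96 h array the slopes of cholesterol synthesis (adjusted p = 1.37e-04) and of the unfolded protein response (0.0208) passed, and without the 12 h array that of NF-kB (0.0313). Without loess the means of cholesterol synthesis (0.0035), NRF2 (0.00259), the unfolded protein response (0.0377) and alveolar and airway markers (0.0249) passed. Of 13 inflammatory genes of NF-kB, 3 were lower and 1 higher (adjusted p = 0.273), with CXCL1 and RELB (-0.40 ± 0.27 SD) lowest and TNFAIP2 at -0.21 ± 0.10 (SD). At 24 h this list's median of -0.17 lay at percentile 0.02. Of 22 genes of cholesterol synthesis, 4 were higher, among them MSMO1 (0.25 ± 0.12 SD), and 2 were lower, among them EBP (-0.14 ± 0.04 SD), with an adjusted p of 0.284. Its median at 48 h was 0.20, above all random lists of like brightness. Of 24 p53 target genes 5 were higher, among them TP53INP1 (0.27 ± 0.19 SD) and TNFRSF10B (0.24 ± 0.10 SD), and 3 were lower, among them PHLDA3 (-0.21 ± 0.06 SD), with an adjusted p of 0.867. Of 21 NRF2 target genes 4 were higher, among them FTL (0.38 ± 0.09 SD), and 3 were lower, among them TXNRD1 (-0.24 ± 0.15 SD), with an adjusted p of 0.922. Of 24 genes of the unfolded protein response and amino acid stress, 4 were higher and 2 lower (adjusted p = 0.867), with HERPUD1 lowest (-0.45 ± 0.15 SD). Of 24 genes of IGF, insulin and PI3K signalling, 3 were higher and 2 lower (adjusted p = 0.922), the latter being TSC1 (-0.35 ± 0.12 SD) and AKT1 (-0.24 ± 0.07 SD). Of 13 epithelial genes of the epithelial-mesenchymal transition 2 were lower, CDH1 (-0.25 ± 0.11 SD) and KRT7 (-0.19 ± 0.10 SD), and 1 was higher (adjusted p = 0.788). Of 13 mesenchymal ones 1 was lower and 1 was higher, TAGLN (0.15 ± 0.08 SD), with an adjusted p of 0.867. None of 14 alveolar and airway markers passed (0 genes, adjusted p = 0.689). Of 5 measured blood cell markers 2 were higher and HBB was lower (-0.42 ± 0.15 SD), with an adjusted p of 0.669. Of the fibroblast and endothelial markers only THY1 was measured (0.23 ± 0.17 SD), so this list was not tested.

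The 4 arrays were compared with each other over all genes, which are not independent replicates. Neighbouring times had Pearson correlations of 0.573 (12 and 24 h), 0.7 (24 and 48 h) and 0.675 (48 and 96 h). For the wider gaps it was 0.464 (12 and 48 h), 0.572 (24 and 96 h) and 0.328 (12 and 96 h). The same dye bias on all arrays enters these correlations as well as any effect of the transfection.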

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

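The tests of explanations in this part, unlike the planned slope tests of the lists, were chosen after the results were seen. Their standard errors are taken over genes measured on the same arrays, which are not independent replicates. They do not measure the spread between cultures or arrays.

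The slope of the log2 ratio per doubling of the hours passed in camera at the preset correlation for 5 gene lists, and none of these calls held with an estimated correlation (adjusted p = 0.711 to 0.919). The median slope was 0.148 for neuroendocrine markers and -0.076 for G2/M and mitosis genes. It was 0.0538 for interferon-response genes, 0.043 for genes of hypoxia and glycolysis, and -0.039 for the microRNA machinery. No group held enough samples for a test of single samples.

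Of 30 reported miR-375 targets 14 were lower, 1 was higher and 15 did not pass, and the list's call was lost with an estimated correlation (adjusted p = 0.925). A dye bias of the probes that is constant over the arrays would leave their ratios still in time, but the median over members of the mean at 24 and 48 h minus the value at 12 h was -0.148 ± 0.036 (standard error), with 25 of 30 members lower than at 12 h. With 96 h included it was -0.0868 ± 0.054, within 2 standard errors of 0, and the planned slope of the list was not called (adjusted p = 0.0671), so these values argue only against such a bias as the whole difference at 24 and 48 h. A bias with brightness would leave them level with genes of like brightness, but without loess the median excess over the 200 nearest genes in brightness was -0.181 ± 0.029 (standard error). A direct effect of the microRNA may be a candidate explanation and stays open with a part played by dye bias, since no time has a replicate and no sites in the transcripts were searched.

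Of 35 ribosomal protein genes 20 were higher, 1 was lower and 14 did not pass, and the list's call was lost with an estimated correlation (adjusted p = 0.925). A bias with brightness left by the normalization may account for the higher ones. The median excess of the members over the 200 nearest genes in brightness was 0.0072 ± 0.023 (standard error), and 2 other normalizations ended or turned the call. No biological explanation was tested for this list.

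At 96 h 33 of 38 liver-type genes and 9 of 12 neuroendocrine markers had a log2 ratio above 0, and the slope call of the latter was lost with an estimated correlation (adjusted p = 0.711). A constant dye bias is argued against for the 28 liver-type genes not among those that first showed the rise. Their mean change from 12 to 96 h was 0.295 ± 0.058 (standard error). Such a bias cancels in the slope, and the neuroendocrine list's slope passed in fry (adjusted p = 0.028). Of its 9 members well above background in both channels on all 4 arrays, 5 rose and 1 fell, adjusted over the list alone. These values argue against a constant dye bias as the whole change with time in this list. Its mean change from 12 to 96 h, 0.534 ± 0.224, does not decide this. The change was 0.405 ± 0.237 over the 9 members well above background in a channel at both times. Without CHGB and SCG3 it was 0.234 ± 0.117. The neuroendocrine list's median at 96 h lay at percentile 100 of random lists of like brightness, which argues against a bias with brightness averaged over the 4 arrays. A bias with the brightness at 96 h alone was not tested, and this percentile had been seen before it was used here. The other genes at least 2-fold higher in the control channel at 48 h than at 12 h numbered 263. Their median log2 ratio at 96 h was -0.03 ± 0.023 (standard error), against 0.456 for 11 liver-type genes, drawn from all 38 members. Genes that rose by 48 h need not rise further by 96 h. This comparison therefore cannot decide whether the treated cultures were only further along the control cells' own time course. That comparison replaced correlations over all genes that had been seen. The 96 h ratio had a correlation of -0.08 with the control channel's change from 12 to 48 h. That of the 48 h ratio with the change from 12 to 96 h was 0.1. An effect of miR-375, cultures further along that time course or a difference between single cultures may be the source. These stay open, since no time has a replicate.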

How the results depend on the processing

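The alternatives were planned before the data were examined, except 20 bins for matching random lists on brightness, which had been the first setting and was replaced after its percentiles were seen. With 20 bins the ribosomal list lay at percentiles 100, 99.8, 99.1 and 99.9 at the 4 times, and reported targets at 32, 0, 0 and 0. Each ratio pairs the miR-375 and control cultures of a time on 1 array, so the tests of mean and slope are paired, and no time has a second pair. The planned site searches and site classes for miR-375 seed matches were not run, since no transcript sequences were provided. Across named genes, 1117 results under the alternatives kept direction and side of the threshold, 296 lost the call, 28 gained one and 27 turned direction. For lists past the threshold in neither setting, 61 of 373 comparisons turned sign, so no direction is given for them. Where a channel is not well above background, ratios are bounds only. The cause was not tested for any of the changes below.

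With Agilent's processed signals 1098 genes were lower and 995 higher (52.5% lower), with the series matrix 1204 and 1103 (52.2% lower), and with offset 0 1357 and 1450. Without loess 1032 were lower and 12095 higher (7.86% lower), and against a 1.2-fold change 1 and 6 (14.3% lower), where YAP1, at -0.30, did not pass. Leaving out 1 time point gave 429 to 1797 lower and 585 to 2385 higher. In the slope, hours in place of log2(hours) called 2 genes, no loess 33, and leave-one-out 3 to 10 with 1 residual degree of freedom. Genes with a computed ratio of at least 2-fold either way at 12, 24, 48 and 96 h numbered 49, 61, 81 and 44 with Agilent's signals, 38, 47, 68 and 252 without loess, 20, 34, 39 and 21 with offset 0, and 39, 49, 73 and 39 with the series matrix. A 1.5-fold threshold gave 21, 55, 140 and 133. Requiring both channels well above background on all 4 arrays left 1 at 12 h and 1 at 24 h. The median correlation between times was 0.808 without loess.

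With an estimated correlation, the adjusted p was 0.925 for the mean of the lists of reported targets, G2/M, DNA replication, interferon and ribosomal genes, 0.919 for the slopes of G2/M, hypoxia and interferon genes, and 0.711 for those of neuroendocrine and microRNA machinery genes. Without loess the adjusted p of the mean was 0.128 for reported targets and 0.558 for interferon genes. The direction turned for G2/M (0.426), DNA replication (0.287), NRF2 (0.00259) and the unfolded protein response (0.0377), and that of ribosomal genes turned with Agilent's signals (0.887) and was not called with the series matrix (0.814). The interferon mean missed the threshold with all probes averaged (0.0517). Its slope missed it with Agilent's signals (0.0868) and the series matrix (0.0821). The hypoxia slope missed it with 12 h against later times (0.167) and Agilent's signals (0.0572), and the neuroendocrine slope without a filter (0.106). The slope of reported targets passed with 12 h against later times (5.79e-05), as did that of DNA replication (0.0411). Without loess the slopes of DNA replication (0.00297) and ribosomal genes (2.28e-05) and the means of cholesterol synthesis (0.0035) and alveolar markers (0.0249) gained a call.

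Leaving out 1 time point gave adjusted p-values of 0.00372 to 0.0989 for the mean of interferon response, 0.0169 to 0.179 for the mean of neuroendocrine markers, 0.0313 to 0.97 for the slope of NF-kB inflammatory genes, 0.000304 to 0.164 for the slope of hypoxia and glycolysis, 0.00304 to 0.367 for the slope of interferon response, 0.00332 to 0.233 for the slope of microRNA machinery, and 5.62e-05 to 0.239 for the slope of reported miR-375 targets. The slope of the NF-kB list turned direction without 12 h (0.0313). Without 96 h the slopes of DNA replication (2.1e-04, up to 0.97), cholesterol synthesis (1.37e-04, up to 0.97) and the unfolded protein response (0.0208, up to 0.856) gained a call.

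Without loess the median of all genes was 0.22. YAP1 was at -0.0590 and did not pass, and YAP1 minus that median was -0.278, against -0.314 with loess. The mean of 25 named genes turned from below 0 to above 0, of which 19 stayed below that median, with these values: AMOTL2 0.16, ANXA8 0.0864, A_24_P230486 0.0616, BIRC3 0.0196, BIRC5 0.23, CDH1 0.15, CDK1 0.14, CDT1 0.00942, DROSHA 0.26, GINS3 0.0474, HERPUD1 0.0583, KIF23 0.16, KRT7 0.24, LOC649545 0.0144, LPCAT1 0.21, NUAK2 0.0253, PHLDA3 0.12, PHLDB2 0.0271, TAOK3 0.0867, TK1 0.32, TNFAIP2 0.34, TNRC6B 0.067, TXNRD1 0.13, TYMS 0.11, UBE2C 0.27. Leaving out 1 time point gave AHSG -0.0399 (without 96 h) to 0.376, and CRYAB -0.305 to 0.00965 (without 96 h), both with the direction turned without 96 h.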

Other observations

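Liver-type plasma protein genes were higher in the miR-375 cells at the late times. The hypothesis that they rise as a group at 96 h came from 10 members whose values had been seen, so the test rests on the other 47 listed genes, of which 28 were measured. Their median log2 ratio was -0.03, -0.03, 0.11 and 0.30 at 12, 24, 48 and 96 h, and 23 of 28 were higher at 96 h. The median at 96 h lay at percentile 100 of random lists of like brightness. This test was written before it was run, but CFB, 1 of the 28, was also a member of the NF-kB list tested earlier. Genes of such a list may move together on the 1 array of that time, which random lists do not allow for. The percentile therefore does not measure the spread between cultures. Over all 38 measured members the medians were -0.05, -0.01, 0.16 and 0.43. At 96 h ASGR1, a receptor that clears glycoproteins from plasma, was at 0.98, ITIH2, a hyaluronan-binding plasma protein, at 0.87, TTR, the thyroid hormone carrier transthyretin, at 0.81, TF (transferrin) at 0.81 and SERPINA1, the protease inhibitor alpha-1-antitrypsin, at 0.78. The fibrinogen chains FGB and FGG were at 0.61 and 0.55, and ALB (albumin) at 0.33. KNG1 was at -0.37 and C3 at -0.20.

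In the control cells too 35 of the 38 measured genes had higher signals at 96 h than at 12 h, the exceptions being CPB2, ASGR2 and FETUB, compared between arrays without replicates and without a test. The median difference from 12 to 96 h over the 38 members was 1.62 (log2) in the control channel and 1.97 in the treated one. AHSG was higher at 96 h by 3 in control and 4.23 in treated cells, and CHGB by 1.65 and 3.67. STMN3 differed by 0.03 in control and 1.80 in treated cells at 96 h, and by -0.96 in control and 0.76 in treated cells at 48 h, both against 12 h. MED18 was higher at 96 h by 2.11 in control and 1.06 in treated cells, and its ratio of 1.23 at 12 h and 1.07 at 24 h compares with 0.18 at 96 h.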
